A study of Mus musculus with 6 samples.

How the data were processed

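The series holds 6 mouse RNA-seq libraries made from T cells sorted out of skin: 4 libraries of regulatory T cells (Tregs) and 2 of effector T cells (Teffs). Per the labels, cells came from mice aged 6 weeks that carry a GFP reporter of FOXP3, the transcription factor that defines Tregs. RNA was purified on columns and turned into cDNA with a SMARTer ultra-low-input kit, per the labels' protocols. The labels do not say whether libraries of a group came from separate animals. The p-values of single genes therefore measure the spread between these libraries, part of which may be technical. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.12, Bowtie2 2.1.0.0, SAMtools 0.1.19.0, HTSeq 0.6.1 and build mm10, without giving the step each was used for. The gene annotation, the strand setting of the counting and the test behind the deposited comparison are not given in the sources used here.

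The authors deposited 1 table with 15109 rows, in which the 6 library columns hold raw whole-number counts per gene, per the file headers and the values. The same table holds the authors' comparison of both groups. It gives a log2 fold change and a mean log2 CPM (counts scaled to library size) per row, which the authors deposited on the log2 scale, per the file headers. It also gives a deposited p-value and a false discovery rate (FDR). The deposited fold changes are positive where Tregs are higher, which was checked against the counts: 97.2% of tested genes had the sign found here. The deposited FDR equals a Benjamini-Hochberg adjustment of the deposited p over all 15109 rows to within 1.2e-07. Values quoted from that comparison are named as coming from the authors' deposited table.

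The table holds 3 rows that name no gene: reads without a feature, reads with several alignments and ambiguous reads. They took 88% to 90.2% of the column totals. Reads with several alignments made up 61.2% to 66.2% of a column, and the counter can enter such a read once per alignment, so this is a share of entries and not of reads. The 3 rows were left out of library sizes and tests. The remaining 15106 genes held 4902126 to 7468778 counts per library. A floor of 3 counts corresponded to 0.397 to 0.581 CPM, depending on the library. Floors and intervals cover counting error only, since PCR copies are not independent molecules.

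Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passing filterByExpr (smallest count 10) were kept, which left 11775. Library sizes were scaled by TMM, with factors from 0.913 to 1.05, and CPM values are on these scaled sizes. The main test was edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest) on group alone, with all 6 libraries and no block on the replicate number. The effect is coded Treg minus Teff, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is the fold change divided by the square root of its F statistic. With 4 libraries against 2, an exact permutation test of a single value cannot go below p = 0.0667 (two-sided), so the test that pools spread across genes was used throughout. A fold against a group with no counts is given as a lower bound, computed against 3 counts over the whole group. With 1 to 3 counts in a group, the ratio of pooled counts is given with its exact 95% counting interval.

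Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 18 biological lists and separately over the cell type lists. Lists with fewer than 3 tested members got values only, which left 8 of the 15 cell type lists for testing. The same lists were tested with camera at an estimated correlation and with fry. At the preset correlation, camera sets list members against other genes, with degrees of freedom from the number of genes and not of libraries. At an estimated correlation the degrees of freedom come from the libraries, so p can rise even where the estimate lies below 0.01. Fry was run in one direction and in its mixed form, which counts differences of members in either direction. The lists, the design, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Foxp3 in every library, up to 12 called genes per direction with the largest fold (mean at or above the median, groups not overlapping, no gene models or antigen receptor segments), up to 4 called members of each list, and 22 genes whatever their result. It gave 24 genes, after leaving out 1 that is not reported here. Other list members given as examples, and genes outside the lists, were chosen after their values were seen.

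Alternatives that changed 1 choice at a time were DESeq2 size factors or upper-quartile scaling, no filter, and a filter at mean CPM 10. Further ones were each library left out in turn, an adjusted p of 0.01, and an added log2 fold threshold of 1. A block on the replicate number also took Treg 3 and Treg 4 out of the group comparison, since no Teff library shares their number. Others changed several at once: DESeq2 1.42.0 with its own size factors and filter, the block on the 4 libraries that share a number, and the authors' deposited comparison. A change of pseudocount applied only to normalized values and was not needed. Alternatives added after the data were seen were a robust prior, edgeR's exact test, limma voom with sample quality weights, a filter of 10 counts in every library, a run close to the deposited comparison, and a run without Treg 3 and Teff 1.

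The scripts were tested on simulated negative binomial counts with the means, library sizes and dispersions of these libraries, in which 200 genes differed. At the dispersions of these data and over 10872 tested genes, edgeR called 6 of 100 genes with a 4-fold difference and 78 of 100 with a 32-fold difference, all in the right direction, along with 13 unchanged genes. DESeq2 called 30 and 96 of these genes, and 187 unchanged ones. At a dispersion of 0.1 and over 11602 tested genes, edgeR called 90 and 100 of 100, along with 9 unchanged genes. DESeq2 called 94 and 100 there, along with 22 unchanged ones. Gene coordinates come from GENCODE vM21 on GRCm38, the assembly that mm10 names. Of the 15106 symbols, 14443 (95.6%) have the same name there.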

Results

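Transcripts were counted in Tregs, the suppressive CD4 T cells that express FOXP3, and in Teffs, the other sorted T cell group, both taken from the skin of mice aged 6 weeks. There were 4 Treg libraries and 2 Teff libraries, and the question put by the design is how the transcriptomes of these populations differ within the skin. Counts in genes came to 6079194, 6289509, 5582022 and 7046685 in Treg 1 to Treg 4 and to 7468778 and 4902126 in Teff 1 and Teff 2. Counts were found for 9602, 9838, 12605 and 11074 genes in the Treg libraries and for 13197 and 11894 genes in the Teff libraries. After thinning to 4902126 counts per library these numbers were 9500, 9729, 12544 and 10929 in Tregs and 13022 and 11894 in Teffs. Libraries varied widely, with a biological coefficient of variation of 1.20 over both groups. A count of 0 in at least 1 library was found for 33.4% of tested genes. Spearman correlations of counts over tested genes were 0.649 to 0.748 between Treg libraries and 0.883 between both Teff libraries. Between a Treg and a Teff library they were 0.7 to 0.815, so Treg libraries were no more like each other than like Teff libraries.

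Foxp3, the gene behind the sort, was found in every Treg library and was low in both Teff libraries. Its level was 103, 233, 154 and 183 CPM in Treg 1 to Treg 4 and 11.3 and 7.17 CPM in Teff 1 and Teff 2. The log2 fold change was 4.19 ± 0.61 (SE). Foxp3 passed the test when adjusted over the list alone (edgeR adjusted p = 0.000533, Treg identity list) and missed the threshold over all genes (adjusted p = 0.131). The gene lies on chromosome X, from 7573644 to 7595245 (GRCm38), and exons of other annotated genes overlap 31.5% of its exonic bases, and how reads from those bases were counted is not given in the sources used here.

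Over all genes, 4 rose and 1 fell in Tregs relative to Teffs among 11775 tested. The 4 higher genes were Ctla4, an inhibitory receptor that competes with CD28 for its ligands, Il1rl1, the IL-33 receptor chain ST2, Klrg1, an inhibitory lectin-like receptor of differentiated T cells, and Cd83, a surface glycoprotein of activated lymphocytes and dendritic cells. Ctla4 stood at 3780 ± 849 CPM (SD, n = 4) in Tregs and 152 ± 21.9 CPM (SD, n = 2) in Teffs, a log2 fold change of 4.64 ± 0.43 (SE). Klrg1 was at 449 ± 149 CPM against 11.5 ± 1.49 CPM, with a log2 fold change of 5.28 ± 0.54. Il1rl1 was at 402 ± 86.8 CPM against 17.5 ± 0.671 CPM, with a log2 fold change of 4.52 ± 0.44. Cd83 was at 1153 ± 419 CPM against 52.3 ± 3.77 CPM, with a log2 fold change of 4.46 ± 0.49. The gene that fell was Ctsw, which encodes cathepsin W, a protease of cytotoxic lymphocytes, at 172 ± 40.5 CPM in Tregs and 1436 ± 392 CPM in Teffs, a log2 fold change of -3.06 ± 0.34. In edgeR's quasi-likelihood test the adjusted p was 0.0378 for Ctla4, Il1rl1 and Klrg1 and 0.0460 for Cd83 and Ctsw, and for each of them all 4 Treg libraries lay on one side of both Teff libraries.

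These genes lie on chromosome 1 (Ctla4, 60887000 to 60915832, and Il1rl1, 40429570 to 40465415), chromosome 6 (Klrg1, 122270596 to 122282882), chromosome 13 (Cd83, 43784775 to 43803132) and chromosome 19 (Ctsw, 5465043 to 5468507) of GRCm38. The number of calls depended on the analysis, in which the genes tested and the scaling differed as well as the test: the authors' deposited table calls 43 genes at an FDR under 0.05, 29 higher and 14 lower in Tregs, and DESeq2 called 159 higher and 59 lower. All 5 edgeR calls are among both of these sets, and all 43 genes of the deposited set are among those of DESeq2. Unadjusted p was under 0.05 for 557 genes in edgeR, where 589 would be expected with no difference. Groups did not overlap for 1767 genes (15%), against 13.3% expected by chance. All Treg libraries lay above both Teff libraries for 649 of these genes and below both for 1118. None of the 5 calls was kept when any single library was left out, while their log2 fold changes stayed at 4.49 to 4.78 (Ctla4), 5.08 to 5.43 (Klrg1), 4.38 to 4.61 (Il1rl1), 4.20 to 4.59 (Cd83) and -3.32 to -2.77 (Ctsw). Without Teff 1, edgeR called Ikzf2 and Lrrc32, both higher in Tregs (adjusted p = 0.0438), and without any other single library it called 0 genes, with 186 to 779 genes at an unadjusted p under 0.05.

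**Figure D1:**
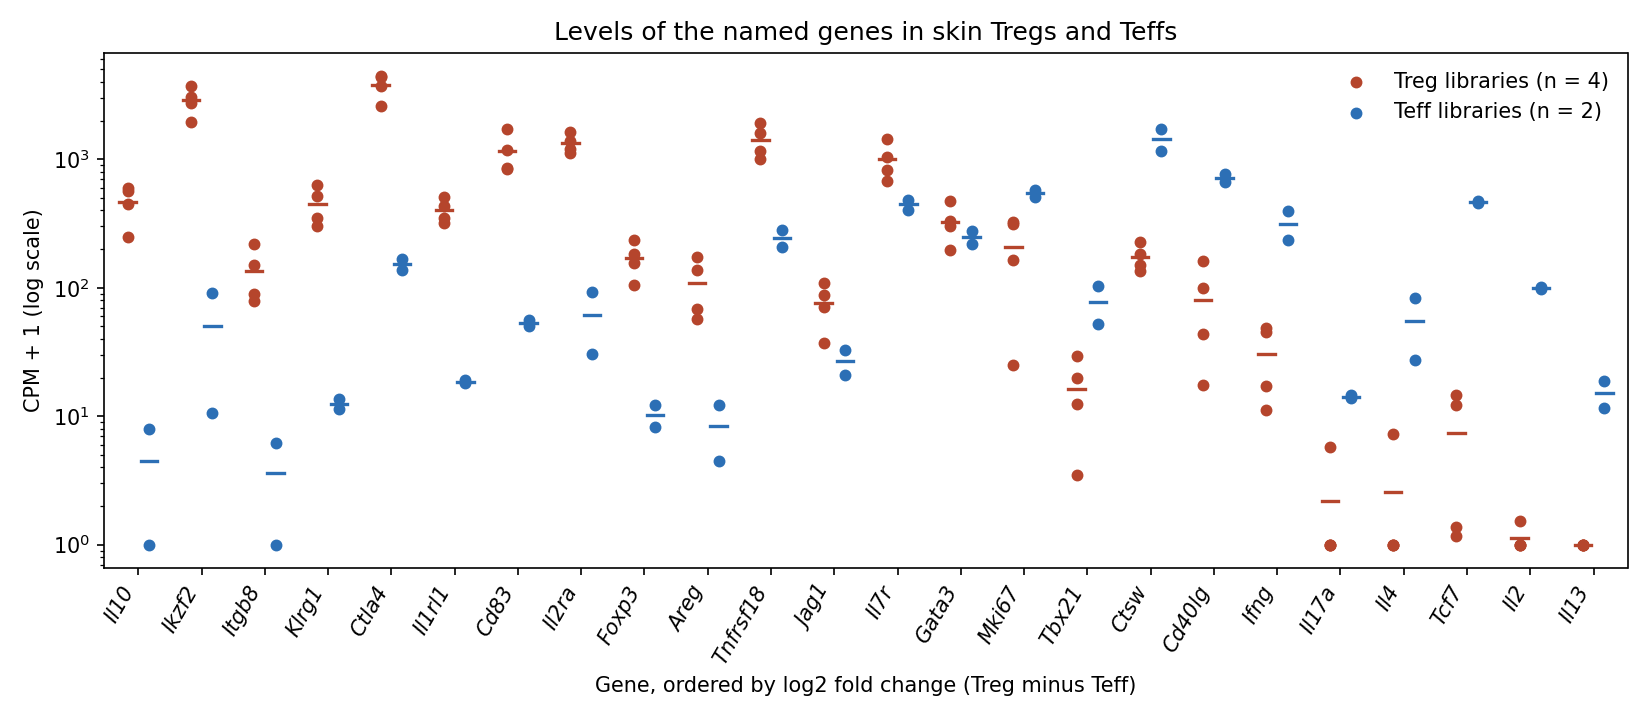
CPM plus 1 (log scale) of 24 named genes in each library, ordered by log2 fold change, with Tregs in red (n = 4), Teffs in blue (n = 2) and bars at group means. Ctla4, Il1rl1, Klrg1 and Cd83 were called higher and Ctsw lower in Tregs, and the other genes missed the threshold over all genes.

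Genes that define Treg identity were higher in Tregs as a group. Of the 16 members tested, 1 (Ctla4) rose over all genes, and 9 rose and 0 fell when adjusted over the list alone. The median log2 fold change was 2.59, and the list passed camera with the preset correlation (adjusted p = 2.22e-39) and with an estimated correlation (adjusted p = 0.0160). Il2ra, the high-affinity chain of the IL-2 receptor, was at 1336 ± 232 CPM in Tregs and 60.8 ± 44.6 CPM in Teffs. Ikzf2, the transcription factor Helios, was at 2877 ± 727 CPM against 49.6 ± 56.7 CPM, and the 2 Teff libraries differed in it. Lrrc32, which encodes the TGF-beta docking receptor GARP, was at 236 ± 15.8 CPM against 2.38 ± 3.37 CPM, with counts in Teff 1 alone among Teffs. Tnfrsf18, the receptor GITR, was at 1414 ± 421 CPM against 245 ± 52.9 CPM. All of these passed when adjusted over the list alone (adjusted p of 0.000533 for Il2ra, 0.000833 for Ikzf2 and Tnfrsf18, and 0.00244 for Lrrc32) and missed over all genes (adjusted p of 0.0890 to 0.288). Exons of an annotated antisense gene overlap 27.2% of the exonic bases of Tnfrsf18.

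Genes of tissue-resident and effector Tregs were also higher in Tregs. Of the 20 members tested, 2 (Il1rl1 and Klrg1) rose over all genes, and 15 rose and 0 fell when adjusted over the list alone. The median log2 fold change was 1.79, and the list passed camera with the preset correlation (adjusted p = 2.22e-39) and with an estimated correlation (adjusted p = 0.00233). Il10, an anti-inflammatory cytokine, was at 463 ± 157 CPM in Tregs and 3.49 ± 4.93 CPM in Teffs, with counts in Teff 2 alone among Teffs (log2 fold change 7.09 ± 1.55, adjusted p = 0.00613 over the list alone and 0.344 over all genes). Areg, a ligand of the epidermal growth factor receptor linked to tissue repair, was at 107 ± 55.3 CPM against 7.34 ± 5.51 CPM (log2 fold change 3.87 ± 0.90, adjusted p = 0.00768 over the list alone and 0.428 over all genes). Tnfrsf9, the receptor 4-1BB, was at 873 ± 325 CPM against 46.3 ± 38.6 CPM, and Tnfrsf4, the receptor OX40, at 2655 ± 658 CPM against 143 ± 120 CPM. Gata3, a transcription factor shared by Th2 cells and tissue Tregs, did not differ beyond the spread, at 325 ± 114 CPM against 247 ± 43.3 CPM (log2 fold change 0.39 ± 0.42).

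Co-stimulatory and inhibitory receptors were higher in Tregs as a list, with members on both sides. Of the 18 members tested, Ctla4 rose over all genes, and 9 rose and 1 fell when adjusted over the list alone. Those that rose over the list alone included Cd27 (508 ± 143 CPM against 47.8 ± 20.7 CPM), Tigit (874 ± 339 CPM against 66.4 ± 17.4 CPM) and Havcr2, the inhibitory receptor TIM-3 (230 ± 102 CPM against 19.5 ± 5.70 CPM). The member that fell was Cd226, an activating receptor that shares ligands with Tigit, at 64.6 ± 52.8 CPM in Tregs and 287 ± 95.5 CPM in Teffs (adjusted p = 0.0228 over the list alone). The list passed camera with the preset correlation (adjusted p = 5.60e-15) and with an estimated correlation (adjusted p = 0.0429). It shares 6 genes with the Treg lists, and its other 12 members had a median log2 fold change of -0.08 and did not pass camera.

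**Figure D2:**
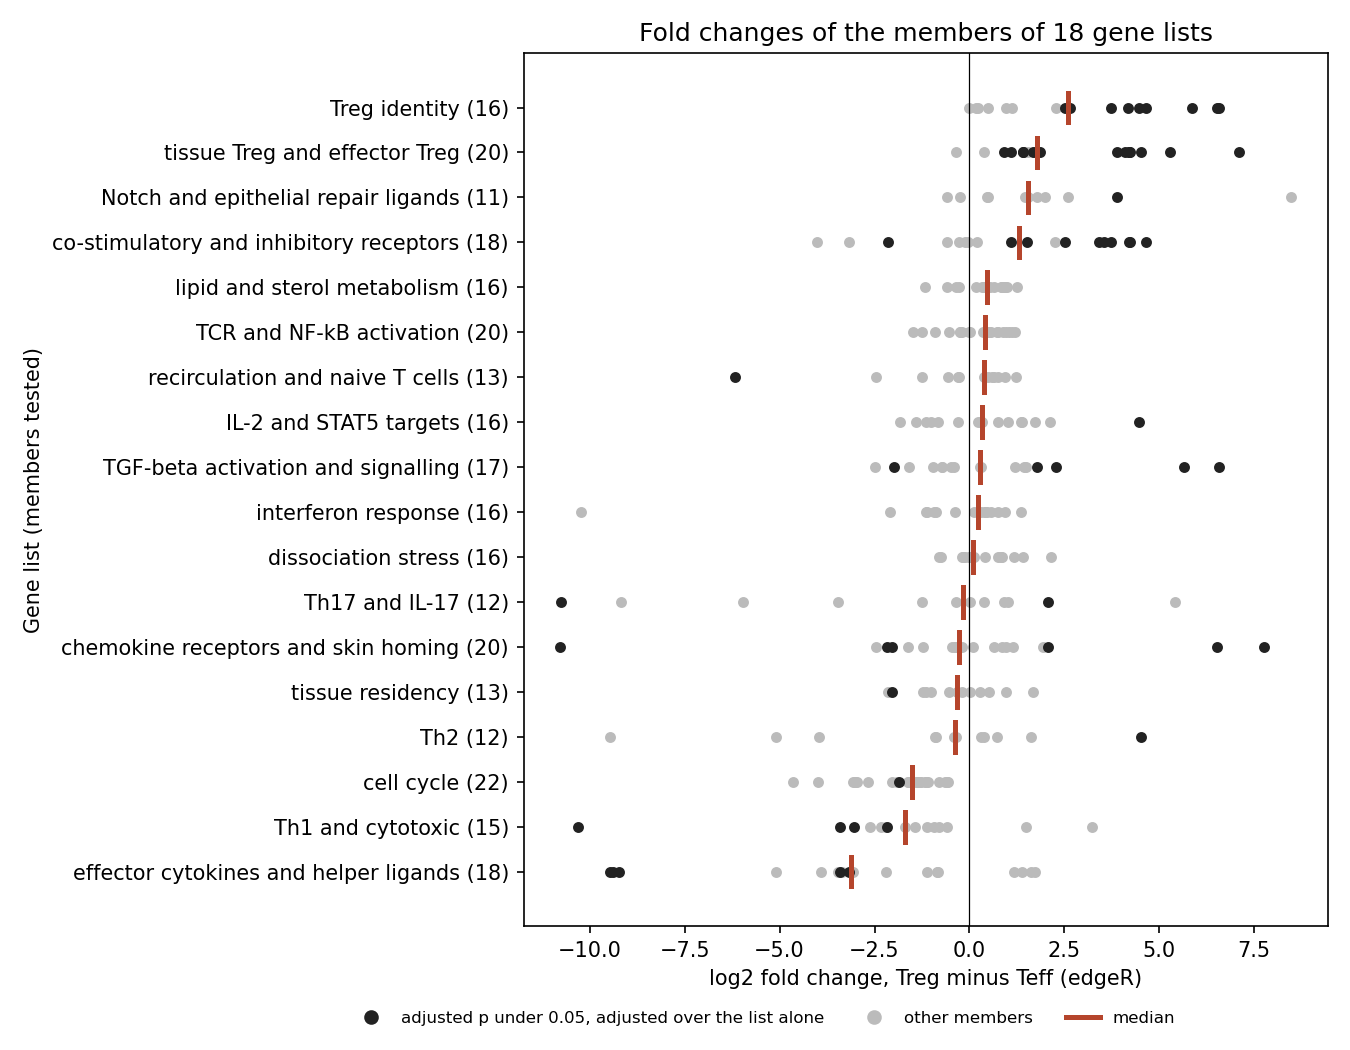
Log2 fold change (Treg minus Teff, edgeR) of every tested member of the 18 gene lists, in black for members past the threshold when adjusted over the list alone and grey for others. Medians (red bars) ran from -3.12 for effector cytokines to 2.59 for Treg identity.

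Th1 and cytotoxic genes were lower in Tregs as a list, with 13 negative and 2 positive log2 fold changes. The positive ones were Prf1 (42.5 ± 64.9 CPM in Tregs against 4.49 ± 1.14 CPM in Teffs) and Ccl3, for both of which the groups overlapped. The granzyme gene Gzmb, kept in the tissue Treg list, was higher in Tregs at 1034 ± 528 CPM against 392 ± 8.94 CPM (edgeR adjusted p = 0.0412 over that list alone). None of the 15 members tested passed over all genes, and 0 rose and 4 fell when adjusted over the list alone. Ifng, the main Th1 cytokine, was at 29.5 ± 19.1 CPM in Tregs and 313 ± 114 CPM in Teffs (log2 fold change -3.40 ± 0.67, adjusted p = 0.00479 over the list alone and 0.283 over all genes). Nkg7, a protein of cytotoxic granules, was at 171 ± 61.4 CPM against 1404 ± 148 CPM, and Cxcr3, a Th1 chemokine receptor, at 145 ± 61.1 CPM against 654 ± 69.8 CPM. Gzma had no counts in any Treg library and was at least 242-fold lower than in Teffs, where it was uneven at 47.0 and 4.26 CPM. Tbx21, the Th1 transcription factor T-bet, did not pass, at 15.3 ± 11.05 CPM against 77.1 ± 36.2 CPM (adjusted p = 0.112 over the list alone). The list passed camera with the preset correlation (adjusted p = 5.76e-13) and with an estimated correlation (adjusted p = 0.0359). Markers of CD8 T cells and of gamma-delta T cells had lower means in Tregs and too few tested members for a list test: Cd8a was at 10.8 ± 21.5 CPM in Tregs and 55.6 ± 14.8 CPM in Teffs, and Cd163l1 had no counts in Tregs and was at 11.6 ± 4.75 CPM in Teffs. An annotated gene on the same strand overlaps 25.9% of the exonic bases of Ifng.

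Effector cytokines and helper ligands were lower in Tregs, with the lowest median of the 18 lists, a log2 fold change of -3.12. None of the 18 members tested passed over all genes, and 0 rose and 5 fell when adjusted over the list alone: Il2, Ifng, Cd40lg, Il13 and Csf2. Il2, the T cell growth factor, was at 101 and 96.9 CPM in the Teff libraries and at 3 counts over all Treg libraries, all of them in Treg 1. The ratio of pooled counts, Treg over Teff, was 0.00123, with an exact 95% counting interval of 0.000254 to 0.00361 (adjusted p = 0.00863 over the list alone and 0.217 over all genes). Cd40lg, the helper ligand for B cells and dendritic cells, was at 79.7 ± 63.8 CPM in Tregs and 717 ± 67.7 CPM in Teffs (adjusted p = 0.0168 over the list alone). Il13 had no counts in Tregs and was at least 122-fold lower than in Teffs, and Csf2 was likewise at least 97.0-fold lower. Il7r, the IL-7 receptor chain, lay on the other side at 995.4 ± 333 CPM in Tregs and 444 ± 54.6 CPM in Teffs and did not pass (adjusted p = 0.0562 over the list alone). The list passed camera with the preset correlation (adjusted p = 2.05e-10) and with an estimated correlation (adjusted p = 0.0160).

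The Th2 and Th17 lists did not pass as groups in one direction (camera adjusted p of 0.982 and 0.489). Among genes with 10 or more counts in every library, which leaves out cytokines without counts in Tregs, both passed as higher in Tregs (adjusted p = 0.00847). With the replicate block on the 4 libraries that share a number, the Th17 list passed as lower instead (camera adjusted p = 0.0352). Of the 12 Th2 members tested, Il1rl1 rose over all genes and over the list alone, and no other member passed. Il4 was at 26.5 and 82.2 CPM in the Teff libraries and was found in Treg 1 alone among Tregs, at 6.31 CPM (adjusted p = 0.272 over the list alone). Of the 12 Th17 members tested, 0 passed over all genes, and 1 rose and 1 fell when adjusted over the list alone. The member that rose was Ccr6, a chemokine receptor, at 711 ± 259 CPM in Tregs and 168 ± 20.3 CPM in Teffs, and the one that fell was Il17f, with no counts in Tregs and at least 323-fold lower than in Teffs, where it was uneven at 58.8 and 11.2 CPM. Il17a was at 13.6 and 12.8 CPM in Teffs and was found in Treg 4 alone among Tregs, at 4.71 CPM.

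Cell cycle genes were lower in Tregs as a list with the preset correlation only. All 22 members had a negative log2 fold change, with a median of -1.51. None passed over all genes, and Top2a, a DNA topoisomerase of dividing cells, fell when adjusted over the list alone, at 175 ± 44.2 CPM in Tregs and 628 ± 44.1 CPM in Teffs (adjusted p = 0.0136). Mki67, which encodes the proliferation marker Ki-67, was at 23.8, 162, 322 and 312 CPM in Treg 1 to Treg 4 and at 506 and 580 CPM in Teff 1 and Teff 2 (log2 fold change -1.40 ± 0.80). The list passed camera with the preset correlation (adjusted p = 2.05e-10) and did not pass with an estimated correlation (adjusted p = 0.143).

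Chemokine receptors did not differ in one direction as a list (camera adjusted p = 0.206). They passed fry's mixed test (adjusted p = 2.42e-05), which does not need members to differ both ways. The mixed test passed for 15 of the 18 gene lists, and not for lipid and sterol metabolism (adjusted p = 0.890), the interferon response (0.108) and dissociation stress (0.549). None of the 20 members tested passed over all genes, and 3 rose and 3 fell when adjusted over the list alone. Ccr3 (142 ± 57.8 CPM in Tregs against 0.678 ± 0.959 CPM in Teffs), Ccr1 (87.7 ± 31.0 CPM against 0.969 ± 1.37 CPM) and Ccr6 were higher in Tregs, and the first 2 of these had no counts in Teff 1. Cxcr3, Cxcr6 (897 ± 362 CPM against 3707 ± 232 CPM) and Cx3cr1, with no counts in Tregs and at least 281-fold lower, were on the other side. Cxcr6 was also the sole member of the tissue residency list to pass over the list alone among 13 tested (adjusted p = 0.0108), and that list did not pass (camera adjusted p = 0.277). Among the 13 recirculation and naive T cell genes tested, Tcf7, the transcription factor TCF-1, fell when adjusted over the list alone. Tcf7 was at 6.36 ± 7.12 CPM in Tregs and 460 ± 11 CPM in Teffs (log2 fold change -6.17 ± 1.39, adjusted p = 0.0280 over the list alone and 0.378 over all genes). That list did not pass (camera adjusted p = 0.223, direction lower), and its median of 0.39 lay on the other side of 0 from its test.

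Genes that activate or transmit TGF-beta did not pass as a list (camera adjusted p = 0.119). Of the 17 members tested, 0 passed over all genes, and 4 rose and 1 fell when adjusted over the list alone. The 4 were Lrrc32, Itgav, Itgb8 and Tgfbr1, and the member that fell was Itgb1. Itgb8, which pairs with the product of Itgav into an integrin that releases active TGF-beta, was at 134 ± 65.8 CPM in Tregs and 2.58 ± 3.65 CPM in Teffs, where its fold rests on 39 counts in Teff 1 and 0 in Teff 2 (log2 fold change 5.65 ± 1.52, adjusted p = 0.0204 over the list alone and 0.619 over all genes). Notch and epithelial repair ligands passed camera with the preset correlation (adjusted p = 0.0276) and not with an estimated correlation (adjusted p = 0.143). The estimated correlation of this list was -0.0324, below the preset one, so a higher correlation was not the reason. Areg alone of the 11 members tested rose over the list alone (adjusted p = 0.0296), and Jag1, a Notch ligand, was at 75.0 ± 30.2 CPM against 25.9 ± 8.44 CPM (log2 fold change 1.53 ± 0.73, adjusted p = 0.354). Fgf7, a growth factor of fibroblasts in this list, was at 227 CPM in Treg 3 and 39.7 CPM in Teff 1 and at 0.969 CPM or less in the other libraries. The list did not pass without Treg 3 (adjusted p = 0.102), without Treg 4 (0.0541) or without Teff 2 (0.0853).

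Activation genes of the T cell receptor and NF-kB pathways passed camera with the preset correlation (adjusted p = 0.0357, median log2 fold change 0.41) and not with an estimated correlation (adjusted p = 0.286). None of the 20 members passed over all genes or over the list alone, and the list kept its side of the threshold under 6 of 16 alternatives. Of the 16 IL-2 and STAT5 targets, Il2ra alone rose over the list alone, and the list did not pass (camera adjusted p = 0.0830). Lipid and sterol metabolism (16 tested, adjusted p = 0.162), the interferon response (16 tested, adjusted p = 0.316) and dissociation stress (16 tested, adjusted p = 0.282) had no member past the threshold over all genes or over the list alone. Without Treg 1 the interferon response was lower (adjusted p = 0.00108) and dissociation stress higher in Tregs (adjusted p = 0.0387), and without Teff 1 lipid and sterol metabolism was higher (adjusted p = 0.0310).

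None of the 8 cell type lists tested was higher or lower as a list in camera (adjusted p of 0.6 to 0.842), but members and libraries differed. Of the 5 NK cell and innate lymphoid cell genes tested, 1 (Il1rl1) rose over all genes and 0 fell, and 1 rose and 3 fell when adjusted over the list alone. Those that fell were Klrk1 (8.72 ± 8.87 CPM in Tregs against 134 ± 10.8 CPM in Teffs), Id2 (974 ± 281 CPM against 1940 ± 21.5 CPM) and Gzma, and this was the 1 cell type list to pass fry's mixed test, which allows members to differ both ways (adjusted p = 0.00058). Fibroblast markers summed to 3115 CPM in Treg 3 and 404 CPM in Teff 1 and to 4.28 to 10.8 CPM in the other 4 libraries, with Col3a1 (1448 CPM in Treg 3 and 89.6 CPM in Teff 1) and Sparc (929 and 146 CPM). Keratinocyte markers summed to 1718 CPM in Treg 3, 286 CPM in Teff 1, 115 CPM in Teff 2 and 40.4 to 69.8 CPM in the other Treg libraries. Markers of CD4 T cells summed to 4599 CPM in Treg 3 and 6869 to 9602 CPM elsewhere. Langerhans and dendritic cell markers, mostly Cd74 (the MHC class II invariant chain, 7131 CPM in Treg 4) and MHC class II genes, summed to 11380 CPM in Treg 4 and 734 CPM in Treg 3, with 1826 and 6143 CPM in Teff 1 and Teff 2. Without both Treg 3 and Teff 1, edgeR called 0 genes (191 at an unadjusted p under 0.05). Of the 18 gene lists, 3 were higher and 3 lower in Tregs in that run, against 5 and 3 with all libraries. Without Treg 3 alone, keratinocyte markers were lower (adjusted p = 0.0174) and Langerhans and dendritic cell markers higher in Tregs (adjusted p = 0.0193).

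**Figure D3:**
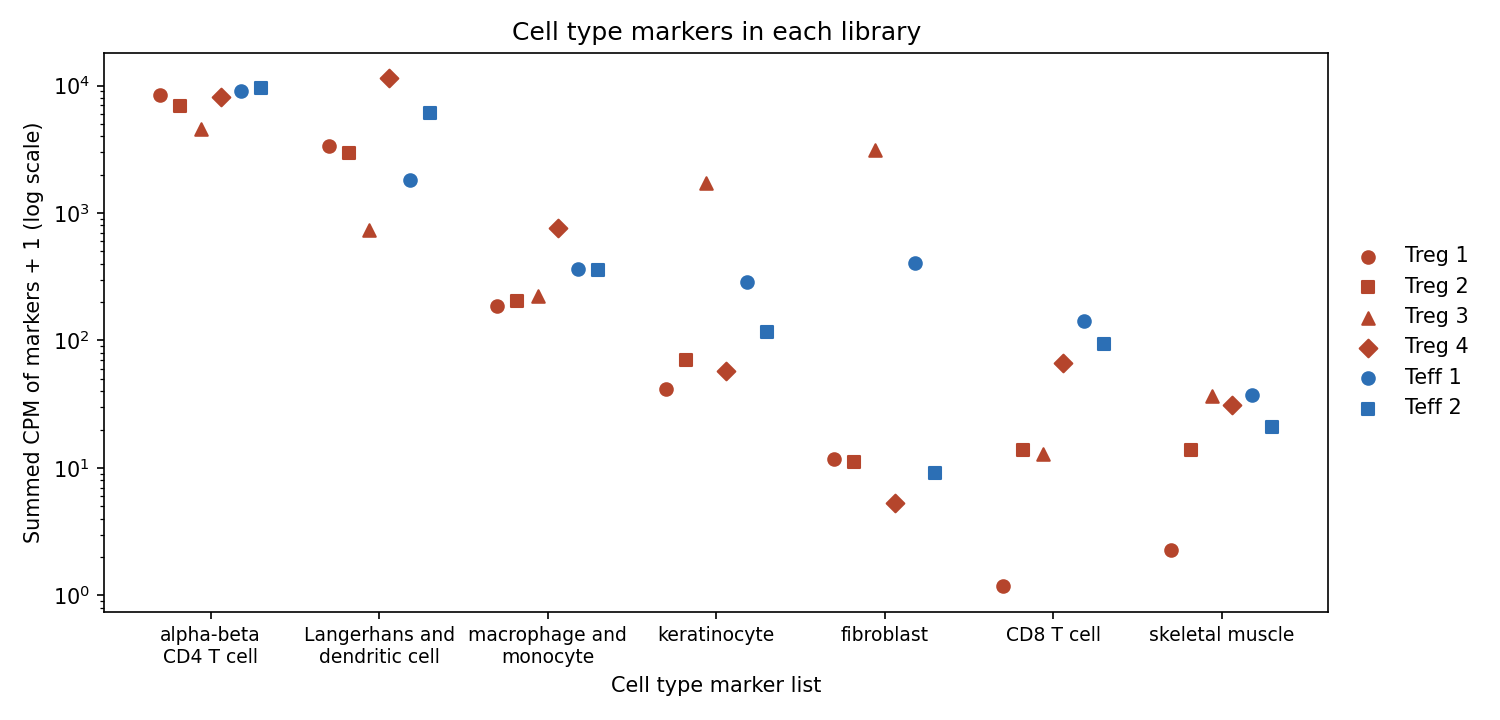
Summed CPM plus 1 (log scale) of the markers of 7 cell types in each library, with Tregs in red, Teffs in blue and a symbol per replicate number. Fibroblast and keratinocyte markers stood apart in Treg 3 (3115 and 1718 CPM) and, at a lower level, in Teff 1 (404 and 286 CPM).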

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

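The outlying libraries were found by a fixed comparison of each library with its group, while the tests of fibroblasts and keratinocytes, of library sensitivity, of read assignment, of the spread added by Treg 3, of partly detected genes and of skeletal muscle were chosen after the result was seen. Treg libraries were compared with each other for 65 measures, and 8 had a library far from the other 3, where chance gives about 3.25. For Il17a, Il4 and Il2 a single library had counts, so the gap was as wide as it can be by construction and the chance figure does not apply, and Il2 rests on 3 counts. These 8 were the fibroblast markers (3120 CPM in Treg 3 against 4.28 to 10.8), the keratinocyte markers (1720 CPM in Treg 3 against 40.4 to 69.8), the neutrophil markers (7.54 CPM in Treg 3 against 0 to 0.143), the macrophage and monocyte markers (764 CPM in Treg 4 against 186 to 221), the red cell markers (24.2 CPM in Treg 1 against 0 to 0.175), Il17a (4.71 CPM in Treg 4), Il4 (6.31 CPM in Treg 1) and Il2 (0.541 CPM in Treg 1). The last 3 had no counts in the other Treg libraries. The red cell list held 1 measured gene and the neutrophil list 2, near 0 in the other Treg libraries, so the chance figure is doubtful there too. A signal outside the main measurement was the share of each column in entries that name no gene, at most 90.2% (Treg 3) and at least 88% (Treg 1).

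Fibroblast and keratinocyte transcripts stood out in Treg 3 and, at a lower level, in Teff 1. A more sensitive library of Treg 3 was predicted to raise T cell markers too, which was not seen. The median log2 ratio of Treg 3 to the other Tregs was -0.759 over 8 CD4 T cell markers (-1.63 to -0.362). Over 23 fibroblast and keratinocyte markers it was 5.48. This cannot decide on sensitivity, since CPM is a share of a library and markers already well detected need not rise. After thinning, Treg 3 had counts for 12544 genes, against 9500, 9729 and 10929 in Treg 1, Treg 2 and Treg 4. Reads of Treg 3 assigned to Teff 1 would alone give 1 ratio of Teff 1 to Treg 3. Of 514 genes found in Treg 3 and not in the other Tregs, 80.7% lay outside the 99% Poisson range of the pooled ratio (23.8%). Of the 514, 21.4% had no counts in Teff 1. Genes that Teffs express themselves were not left out. A smaller share of assigned reads beside Teff 1's own transcripts therefore cannot be excluded. That fibroblasts and keratinocytes, or their RNA, were in the sorted sample stays open: 22 of the 23 markers (95.7%) were highest in Treg 3 among Tregs and 21 of the 23 were higher in Teff 1 than in Teff 2, but these are the markers in which the pattern was seen, so they do not test it. The most abundant were Col3a1 (1448 CPM in Treg 3) and Sparc (929 CPM). The cells were sorted by FACS, and the labels do not give the gates that would remove such cells. The design gives no biological group that sets Treg 3 apart, so no biological explanation was tested.

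The quasi-likelihood test called 5 genes, where the authors' deposited comparison holds 43 and DESeq2 called 218. The choice of test, along with its own estimate of the dispersions, changed the number. With the same scaling, edgeR's exact test, added after the result was seen, called 75 of the same 11775 genes. Among these were 42 of the 43 deposited ones. Genes detected in some libraries only may also account for part of the difference. A refit on the 6571 genes with 10 or more counts in every library called 30, against 9 from adjusting the original p-values over these genes. The common dispersion fell from 1.45 to 0.342, but this filter drops genes with uneven counts, so a fall was to be expected. Whether Treg 3 adds more to the spread than Treg 1 or Treg 2 cannot be told apart, since the common dispersion was 1.17 without Treg 3, 1.19 without Treg 1 and 1.20 without Treg 2, against 1.39 without Treg 4 and 1.45 with all libraries, and 0 genes were called without Treg 3 in edgeR (779 at an unadjusted p under 0.05). Of the 15 splits of the 6 libraries into 4 and 2, only the real one (1 of 15) gave as many edgeR calls as 5, and the highest other gave 3 (Treg 3 and Teff 1 against the rest). There are too few splits for a share under 0.05. For DESeq2, 6 of the 15 splits gave 218 or more calls, the highest 1002 with Treg 1 and Treg 2 set apart. This may reflect a structure of the libraries or false calls of the test, and these were not told apart. On simulated counts with the dispersions of these data, DESeq2 called 187 unchanged genes and edgeR 13. At a dispersion of 0.1 these were 22 and 9. The low number of calls does not show that the groups were alike. Of the gene lists, 5 stayed past the threshold in 16 of 16 alternatives, but these lists are not separate results. The Treg identity list holds Foxp3, the gene behind the sort, and the effector cytokine list shares genes with the Th1 and cytotoxic list. The co-receptor list shares 6 genes with the Treg lists, and its other 12 members had a median log2 fold change of -0.08. All alternatives drew on the same 6 libraries. How many genes differ biologically between Tregs and Teffs stays open.

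Neb, which encodes the giant muscle protein nebulin, was chosen after its values were seen. It was at 583, 652, 1249 and 1620 CPM in Treg 1 to Treg 4 and 25.7 and 24.2 CPM in Teff 1 and Teff 2 (log2 fold change 5.36 ± 0.63, edgeR adjusted p = 0.0568), and its FDR in the authors' deposited table was 1.78e-06. Skeletal muscle in the Treg samples would bring its other transcripts, but 6 muscle markers had a median log2 fold change of -0.157 and a highest one of -0.0925, against 5.31 for Neb on the same scale, and none exceeded 24.5 CPM in a Treg library. Reads of an overlapping gene are also argued against, since another annotated gene overlaps 0.169% of its exonic bases. Higher transcription of Neb in skin Tregs stays open as a hypothesis, along with technical explanations that were not tested, such as reads shared with other genes.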

How the results depend on the processing

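The robust prior, the exact test, voom with quality weights, the filter of 10 counts in every library, the run that keeps entries naming no gene, and the run without Treg 3 and Teff 1 were chosen after the result was seen, and the other alternatives were fixed beforehand. The Treg identity, tissue Treg, Th1 and cytotoxic, effector cytokine and co-receptor lists kept their direction and stayed past the threshold in 16 of 16 alternatives, with highest adjusted p of 0.016, 0.00233, 0.0359, 0.016 and 0.049. Cell cycle did so in 14 of 16, Notch and repair in 7 and T cell receptor activation in 6. For named genes, 373 comparisons with an alternative gave the same call, 57 gained one, 41 lost one and 0 reversed. Upper-quartile scaling moved the median of all log2 fold changes by -0.11, the replicate block by -0.54 (6 libraries) and -0.39 (4 libraries), and voom with quality weights by -0.33.

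Main counts were 4 genes higher and 1 lower in Tregs. They were 159 and 59 with DESeq2, 17 and 2 with no filter, 29 and 14 in the authors' deposited comparison, 46 and 29 with edgeR's exact test, 24 and 13 with voom and quality weights, 21 and 9 with 10 counts in every library, and 30 and 19 with entries naming no gene kept, no filter and the exact test. At an adjusted p of 0.01 both were 0 (557 at an unadjusted p under 0.05). Without Treg 3 and Teff 1 both were 0 in edgeR (191 at an unadjusted p under 0.05). With any single library left out, 0 to 2 were higher and 0 lower (186 to 779 at an unadjusted p under 0.05). Leaving out a library gives fewer samples, and where 1 Teff library is left it is assumed to vary like the Tregs. Among genes with a mean at or above the median, the self-test called 78 of 100 with a 32-fold difference at the full size. It was not run at a smaller one.

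With the replicate block on all 6 libraries, 9 genes were higher and 6 lower, and 2 cell type lists were lower (macrophages and keratinocytes). Of the 5 main calls, that fit kept 4 and lost Ctsw. With the replicate block on the 4 libraries that share a number, 0 were higher and 1 (Tcf7) lower, with 1 cell type list lower (macrophages) and the Th17 list lower too (adjusted p 0.0352, over its alternatives 0.00847 to 0.906). The labels do not say whether libraries with the same number share an animal, and with 2 Teff libraries the values cannot show it. Both block fits compare Treg 1 and Treg 2 with Teff 1 and Teff 2, since no Teff library has number 3 or 4. Under these fits, in that order, the direction reversed for tissue residency (adjusted p 0.758, 0.895), the interferon response (0.555, 0.735), NK cells and ILCs (0.512, 0.467) and fibroblasts (0.512, 0.877). Leaving out Treg 3 alone also reversed NK cells and ILCs (camera adjusted p 0.673) and fibroblasts (0.373). It did not reverse tissue residency or the interferon response. Other causes were not tested.

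Of the 18 gene lists, 5 were higher in Tregs. This became 7 with 10 counts in every library, 6 with no filter, 4 with upper-quartile scaling and with either replicate block, 3 with the stricter filter, 3 without Treg 3 and Teff 1, 3 with an estimated correlation, 3 with fry and 3 to 5 with single libraries left out. None of the 8 cell type lists tested was lower in Tregs. With no filter 1 was, the gamma-delta T cell list (adjusted p 0.00311), which had too few members for the main test. With single libraries left out, 0 to 1 were lower (keratinocytes without Treg 3, gamma-delta T cells without Teff 2) and 0 to 1 higher (Langerhans and dendritic cells without Treg 3).

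Other reversals of direction were in lists that missed the threshold. With the stricter filter these were Th2 (0.156) and Th17 (0.503). With 10 counts in every library they were Th2 (0.00847, then higher), Th17 (0.00847, then higher), recirculation (0.8291), chemokine receptors (0.842), TGF-beta (0.8005), interferon (0.8005) and Langerhans and dendritic cells (0.867); this filter drops cytokines with no counts in Tregs. Without Treg 3 and Teff 1 they were recirculation (0.989), interferon (0.989) and NK cells (0.334). NK cells also reversed with no filter (0.265) and fry (0.891), and fibroblasts with fry (0.998). Leave-one-out ranges in which a direction reversed were 0.0387 to 0.906 for dissociation stress, 0.141 to 0.84 for NK cells, 0.0721 to 0.861 for macrophages, 0.0174 to 0.811 for keratinocytes and 0.0635 to 0.682 for fibroblasts. The cause was not tested.

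Depth limits what a count of 0 means: 3 counts are 0.397 to 0.581 CPM, and 33.4% of tested genes had a 0 in at least 1 library. The change of pseudocount was not run, since the values are counts.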

Other observations

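The genes in this part were chosen after the result was seen, and the run that follows the deposited comparison was added then as well. Outside the gene lists, the genes past an FDR of 0.05 in the authors' deposited table included Fam46a (361 ± 61.8 CPM in Tregs, 24 ± 14.8 CPM in Teffs), N4bp1 (573 ± 68 against 76.7 ± 2.52), Lgmn (134 ± 57.7 against 3.37 ± 3.66) and Ubash3b (402 ± 160.5 against 55.8 ± 8.20) on the higher side. Bicd1 and Magi1 had no counts in Teffs and were at least 256-fold and at least 252.5-fold higher in Tregs, against 3 counts over the group. Both were uneven in Treg 1 to Treg 4, Bicd1 at 152, 50.4, 32.8 and 19.5 CPM and Magi1 at 7.40, 49.1, 108 and 70.6 CPM. On the lower side were Cd7 (67.3 ± 65.2 CPM against 709 ± 118), Amica1 (99.8 ± 53.1 against 730.5 ± 172), Sorl1 (67.3 ± 40.4 against 490.5 ± 55.1) and Evl (22.9 ± 8.92 against 198 ± 2.47). Hid1 had no counts in Tregs and was at least 374-fold lower. None of these passed in edgeR's quasi-likelihood test over all genes, where N4bp1 came nearest of those named here (adjusted p = 0.0606).

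With entries that name no gene kept, no filter and edgeR's exact test, 49 genes were called, among them 42 of the 43 in the authors' deposited table. Fold changes were within 0.0261 (log2) of the deposited ones over 15106 genes.

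The 2 Teff libraries differed in several Treg genes: Ikzf2 was at 89.6 CPM in Teff 1 and 9.50 CPM in Teff 2, Tnfrsf4 at 228 and 58.7 CPM, and Il2ra at 92.4 and 29.3 CPM, while Foxp3 was at 11.3 and 7.17 CPM and Il10 at 0 and 6.98 CPM.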
